A study of Mus musculus with 2 samples.

How the data were processed

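The samples were 2 H3K4me3 ChIP-seq libraries from livers of embryos at 11.5 days, each a pool of mixed sex from the strain B6NCrl, with a fragment size range of 300 to 500 bp, per the labels. They formed 1 group of 2 biological replicates. The labels list possible controls, which were not used here. Per the submitters' notes on the files, the list of replicate 1 was made from its alignments and 2 other input files, that of replicate 2 from its alignments and 1 other file, and the pooled list from both alignments and 2 other files. These other files carry no description in the notes and are probably controls. The list of replicated peaks was derived from the other 3 lists. The peak caller, its version and the rule for a replicated peak are not given in the sources used here.

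All 4 files were in narrowPeak format on mm10, per the file notes deposited with them. The deposited score of each peak is a whole number assigned by the authors' peak caller and was not used. The signal value was read as a ratio, the fold enrichment of ChIP over control computed by the authors, on a linear scale. The sources used here do not state this reading for these files, and the controls are presumed. The value served to rank, filter and describe peaks within their own list, and levels were not compared between lists. A pair of further deposited columns hold the −log10 p-value and the −log10 q-value of each peak as given by the authors; they were checked for range only. A q-value over 0.05 was held by 3.98% of replicate 1 peaks, 4.87% of replicate 2 peaks, 3.46% of pooled peaks and 0.223% of replicated peaks, so the lists were not cut at that value. The deposited summit position of each peak (an other unit, bp from the peak start) was not used. All 24196 replicated peaks had the coordinates of a pooled peak, and 0 peaks had the same coordinates in both replicates. No reads or counts were in the files, so depth per sample is unknown, and a missing peak may be a weak one.

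Genes came from GENCODE mouse release M21 on the same build, with 21911 protein-coding symbols on 21 main chromosomes, and sequence from the GRCm38 reference. A gene was marked when a peak lay within 1 kb of any of its annotated starts. Peaks up to 1 kb apart were merged into domains, and the broadest domain at a gene gave its breadth. Distal peaks lay over 5 kb from any start of any gene type. CpG content was measured over the 500 bp to each side of the 5' end of the gene model, whereas a peak counted at any start. A promoter was CpG-rich with an observed to expected CpG ratio of at least 0.6 and a GC share of at least 0.5 there. Overlap between lists needed 1 bp, and its chance level came from 20 shuffles within chromosomes. Shares carry Wilson 95% intervals. Marking of the 22 fixed gene lists (10 to 39 coding members) was tested with Fisher's exact test, two-sided, against all other coding genes, and breadth with the percentile of the list's median among 10000 random lists of marked genes of the same size, the smallest possible p being 0.0002. Lists with fewer than 3 marked genes were not tested for breadth. Both were adjusted by Benjamini-Hochberg over the lists at a false discovery rate of 0.05. An exact conditional test within CpG-rich and CpG-poor promoters served as an alternative. Odds ratios of the gene lists, also those within CpG classes, had 0.5 added to each cell, so they differ from uncorrected ratios. The odds ratio between CpG-rich and CpG-poor promoters had nothing added. The imprinted list has 4 members that are not protein-coding in the annotation, and C5 of the coagulation list had no match; these stayed out of the tests.

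The gene lists, distances, tests and most alternatives were fixed before the data were examined. Genes named in the text were those at the 20 broadest domains, the 2 members of each list with the broadest domains and its first 2 unmarked members, the nearest genes of the 5 distal peaks of highest fold, and the 5 genes of highest fold with a promoter peak in 1 replicate only. Others were named after their values were seen: the remaining marked and unmarked list members mentioned beside them, the gene families, and the non-coding genes. The alternatives were each replicate alone, the pooled list, peaks at or above the median fold, an overlap of 50% of the shorter peak or of both, shuffling over the whole genome, 0.5 and 2.5 kb to a start, only the 5' end of the gene model, merging on overlap only or up to 3 kb, 2.5 and 10 kb for distal peaks, a CpG window of 1000 bp to each side, and the CpG classes. A further pair of alternatives, without promoters of repeated sequence and with domains at 1 coding gene only, was chosen after seeing the data. Repeated sequence was counted as the share of 50 bp windows around the 5' end of the gene model that occur elsewhere in the reference.

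The tests were checked on simulated data with planted effects. For the marking of gene lists, among 22000 simulated genes with 66% marked, lists of 20 members planted at 97% were called in 89.2% of cases, lists planted at 25% in 85%, and unchanged lists in 0.625%. For domain breadth, again among 22000 genes, lists planted 2.2-fold broader and marked at 97% were called in 92.5% of cases and unchanged ones in 0.938%. Broader lists marked at 25% were left out of this rate, so it does not cover lists with few marked members. Fewer random lists were drawn here than for the real lists. For the replicate overlap, 50% planted among 4000 peaks returned 50.5%. Lists of CpG-rich promoters with no other effect were called in 99.5% of cases when CpG classes were ignored and in 0.5% within them. Both rates counted unadjusted p-values of single lists. Nearly all CpG-rich promoters were marked in this simulation, so no such list could be called higher within classes. The 0.5% therefore says nothing about calls as higher. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and bedtools 2.31.1. Peaks on unplaced or unlocalized scaffolds (14, 9, 14 and 9 in the lists of replicate 1, replicate 2, the pooled and the replicated peaks) stayed out of all analyses of genes.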

Results

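Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped histone H3 trimethylated at lysine 4 (H3K4me3), a modification found at the promoters of genes, in the liver of mouse embryos at 11.5 days of gestation. At this age the liver holds hepatoblasts, the precursors of hepatocytes, and is also a site of blood formation. Each of the 2 samples was a pool of male and female embryos of the strain B6NCrl, and the labels call them biological replicates. Replicate 1 combined the livers of 109 embryos, and the pool size of replicate 2 is not given in the sources used here. The analysis used 4 peak lists in mm10 coordinates. The list of replicate 1 held 32326 peaks over 36.4 Mb, and that of replicate 2 held 28486 peaks over 34.0 Mb. A list called on both replicates together held 31316 peaks over 39.1 Mb, and the list of replicated peaks kept 24196 of these, over 37.2 Mb. Of the replicated peaks, 866 overlapped no peak of the replicate 1 list and 1519 none of the replicate 2 list. A replicated peak was therefore not always called in each replicate's own list. Results are for the replicated list unless stated, and pairs of values in parentheses are from the lists of replicates 1 and 2. Fold enrichment is the authors' signal value for a peak, read as a ratio although the sources used here do not state it for these files. The files hold peaks and no read counts, so the sequencing depth is unknown, and every interval covers the counting error of peaks or genes only. With 1 group of samples there was no comparison between conditions. Genes and peaks are not independent replicates, so each p-value describes how gene groups differ within these lists.

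The first question was which promoters carried the mark. H3K4me3 lay at the promoters of 14533 of 21911 protein-coding genes (66.3%, Wilson 95% interval 65.7 to 67.0), counted as genes with a peak within 1 kb of any annotated start. The lists of replicates 1 and 2 gave 14655 and 14536 genes, of which 14429 were the same genes. Of the 14533 genes of the replicated list, 14415 were marked in both of these lists. Another 226 genes had a promoter peak in replicate 1 only and 107 in replicate 2 only, whereas 7149 had one in neither. Conversely, 65.6% of all replicated peaks lay at a coding start (interval 65.0 to 66.2), against 6.41% when the peaks were shuffled within chromosomes. This share was 56.4% in replicate 1 and 61.7% in replicate 2, and it was 91.8% among peaks at or above the median fold enrichment. Peaks at coding starts had a median width of 1828 bp and a median fold enrichment of 31.5, and the peaks in introns, 12.5% of the list, had medians of 477 bp and 4.43.

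Genes with a promoter rich in CpG dinucleotides were marked almost throughout. The CpG class was taken at the 5' end of the gene model, whereas a peak at any start counted. Of 9724 genes with a CpG-rich promoter, 9585 had a peak (98.6%), against 4948 of 12187 genes with a CpG-poor promoter (40.6%). The peak may lie at a start other than the one classed, and the contrast was not computed for peaks at the 5' end only. The shares in replicate 1 were 98.7% and 41.5%, and those in replicate 2 were 98.5% and 40.7%. The odds ratio was 101, with a p-value by Fisher's exact test, two-sided, too small to be represented as a number. The median ratio of observed to expected CpGs at the 5' end was 0.707 for marked and 0.170 for unmarked genes. Because CpG content separated the genes this strongly, every gene list was also tested within the CpG-rich and CpG-poor classes. Those tests carry the same limit, since they class the 5' end and count peaks at any start. Among families of genes used in sensory or keratinized cells, 2 of 1134 olfactory receptor genes, 1 of 330 vomeronasal receptor genes, 0 of 57 keratin-associated protein genes and 9 of 53 keratin genes (11 and 8 in replicates 1 and 2) had a promoter peak. All 78 genes of mitochondrial ribosomal proteins and all 19 Sox transcription factor genes had one. These families were chosen after their values were seen, and repeated sequence in their promoters was not taken into account.

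Of 22 gene lists fixed before the data were examined, those of the main cell types of the fetal liver were among the most completely marked. The hepatoblast list had a promoter peak at 29 of 30 genes (29 and 29 in replicates 1 and 2; Fisher's exact test against all other coding genes, two-sided, odds ratio 10.003, adjusted p = 0.000909). The erythroid list had 27 of 28 (27 and 27; odds ratio 9.32, exact test, adjusted p = 0.00112). The list of haematopoietic stem and progenitor cells had 19 of 20 (20 and 19; odds ratio 6.61, exact test, adjusted p = 0.00907), and the list of mesenchyme, stellate and mesothelial cells 15 of 16 (15 and 14; odds ratio 5.25, exact test, adjusted p = 0.0252). Adjustment was by Benjamini-Hochberg over the 22 lists. Marked hepatoblast genes included the transcription factors Hnf4a, Foxa2, Prox1 and Hhex and the genes of the secreted proteins albumin (Alb) and alpha-fetoprotein (Afp). Marked erythroid genes included the transcription factors Gata1, Klf1 and Tal1, the erythropoietin receptor Epor and the globin genes Hba-a1 and Hbb-bt. The nearest peak at Hba-a1 lay 0.551 kb from its start. The haem biosynthesis list had 10 of 11 members marked (10 and 10), the megakaryocyte list 9 of 10 (9 and 9) and the endothelial list 13 of 16 (13 and 14); none of these 3 passed the threshold. Among peaks at or above the median fold, which marked 54.4% of all coding genes, 16 of 30 hepatoblast genes (odds ratio 0.952), 8 of 16 mesenchymal genes (0.837) and 12 of 20 progenitor genes (1.23) stayed marked, and all 3 calls were lost. The progenitor and mesenchymal calls were also lost with 1 start per gene (the 5' end of the gene model), and the mesenchymal call in replicate 2 alone and, with an odds ratio of 4.42, without promoters of repeated sequence.

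The unmarked members of these lists were few. Hbb-y, an embryonic beta-like globin gene at chromosome 7, 103851749 to 103853216, had no peak within 1 kb of its start in either replicate, and the nearest replicated peak lay 10.2 kb away. Slc25a37, which encodes the mitochondrial iron importer mitoferrin 1, is at chromosome 14, 69241848 to 69285112, and was the only unmarked haem biosynthesis gene. All of the 50 bp windows of its promoter occur elsewhere in the genome. Serpina1a, which encodes alpha-1 antitrypsin, was the only unmarked hepatoblast gene, and 41.3% of its promoter windows are repeated. Ptprc, the gene of the leukocyte antigen CD45, had a peak of 0.259 kb in replicate 1 only. Dcn, which encodes the matrix protein decorin, was the only unmarked gene of the mesenchymal list, and its nearest peak lay 165 kb away.

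**Figure D1:**
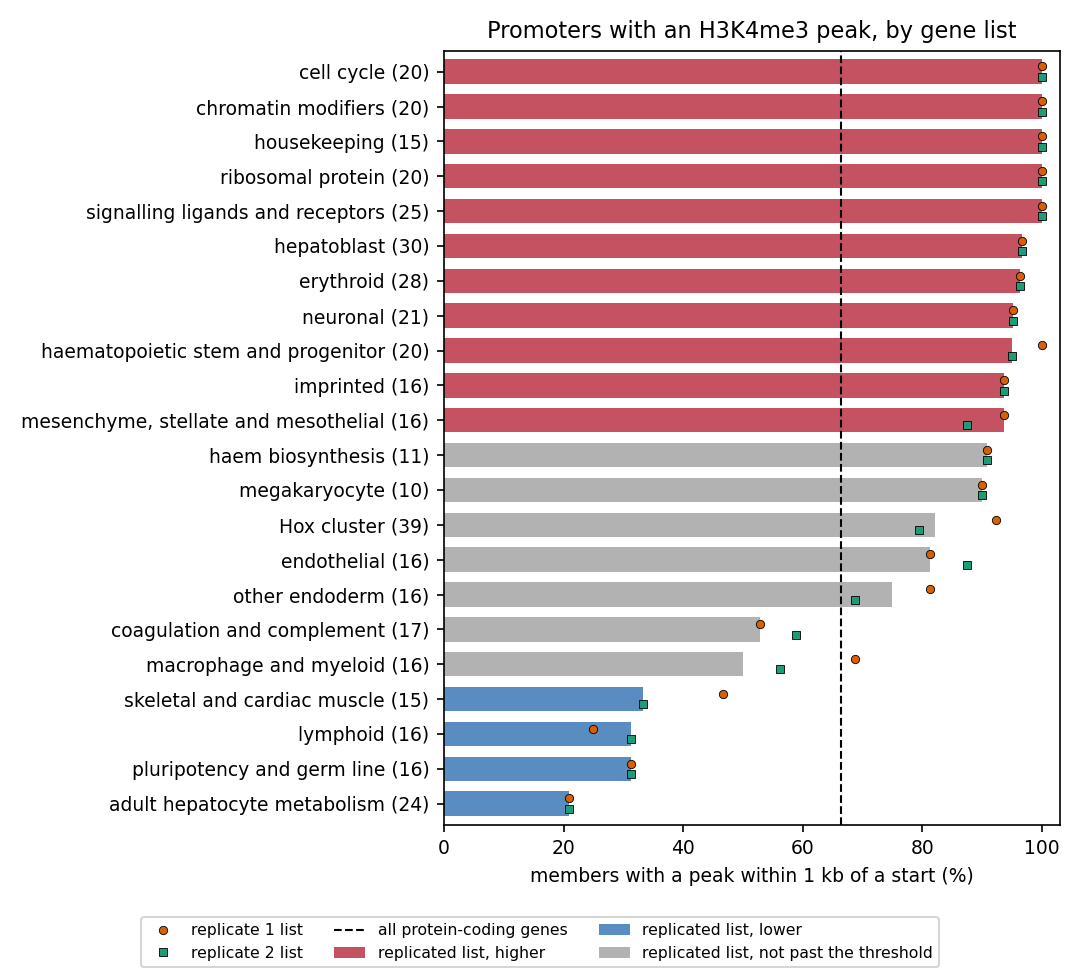
Share of the members of each gene list with an H3K4me3 peak within 1 kb of a start (x axis, percent). Bars are the replicated list, coloured by the call of Fisher's exact test, and circles and squares are replicates 1 and 2, and the dashed line is the share of all coding genes, 66.3%, with adult hepatocyte metabolism lowest at 20.8%.

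The lists marked less often than other genes were those of adult hepatocyte metabolism, lymphoid cells, muscle, and pluripotency and germ line. The adult hepatocyte metabolism list had a promoter peak at 5 of 24 genes (5 and 5 in replicates 1 and 2; odds ratio 0.143, exact test, adjusted p = 0.000141). The unmarked ones included the cytochrome P450 genes Cyp2e1 and Cyp3a11, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and Cps1, the first enzyme of the urea cycle. The marked ones were Glul (glutamine synthetase), with a domain of 3.20 kb, Ass1 with 1.48 kb, and Hpd, Fbp1 and Pah with 0.419, 0.432 and 0.239 kb. The lymphoid list had 5 of 16 (4 and 5; odds ratio 0.243, exact test, adjusted p = 0.0106), with no peak at Cd19 or Cd79a. The skeletal and cardiac muscle list had 5 of 15 (7 and 5; odds ratio 0.266, exact test, adjusted p = 0.0191), with none at Myod1 or Myf5, the factors of muscle commitment, although Myod1 had a peak of 0.29 kb in replicate 1. The list of pluripotency and germ line genes had 5 of 16 (5 and 5; odds ratio 0.243, exact test, adjusted p = 0.0106), with none at Pou5f1 or Nanog. Within CpG classes all 4 odds ratios stayed below 1, with the lymphoid (0.634) and muscle (0.396) calls lost and the adult hepatocyte (0.320, exact test, adjusted p = 0.0496) and pluripotency (0.306) calls kept. The muscle call was also lost in replicate 1 alone (odds ratio 0.437), in the pooled list (0.428), at 2.5 kb (0.333) and with 1 start per gene (0.312).

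The macrophage, endothelial, megakaryocyte and coagulation lists did not pass the test. The macrophage and myeloid list had 8 of 16 (11 and 9), with no replicated peak at Adgre1, which encodes F4/80, or Lyz2, lysozyme. The endothelial list lacked peaks at Stab2 and Lyve1, both genes of sinusoidal endothelium, and the megakaryocyte list at Ppbp. The coagulation and complement list had 9 of 17 (9 and 10), with peaks at the fibrinogen gene Fgg and at Plg but none at F7 or F9 in the replicated list. Within CpG classes the endothelial list (odds ratio 3.29) and the megakaryocyte list (odds ratio 5.13) passed the threshold as higher. Among peaks at or above the median fold the macrophage list (2 of 16) and the coagulation list (0 of 17) passed it as lower and the haem biosynthesis list (10 of 11) as higher, and the macrophage list also did so as lower with 1 start per gene.

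The lists of other lineages differed in how often they were marked. The neuronal list had a peak at 20 of 21 genes (20 and 20; odds ratio 6.95, exact test, adjusted p = 0.00907), including Dlx2, Pax6 and Neurog2, and only Phox2b had none. The nearest replicated peak lay 2.39 kb from a start of Phox2b. The median fold enrichment at the marked neuronal genes was 8.89, against 39.7 over all marked coding genes. Lists of liver cells covered a wide range of the same value: 30.0 for erythroid, 16.6 for hepatoblast, 16.6 for mesenchymal, 7.35 for coagulation, 5.55 for adult hepatocyte and 4.64 for megakaryocyte genes. With peaks below the median fold left out, 5 of the 21 neuronal genes stayed marked and the list passed the threshold as lower. The same filter made the Hox clusters (7 of 39), the other endoderm list (2 of 16) and the endothelial list (3 of 16) lower. The Hox list as a whole, at 32 of 39, had 36 genes marked in replicate 1 and 31 in replicate 2, and its adjusted p of 0.0567 by Fisher's exact test missed the threshold, which it passed as higher in replicate 1 alone, in the pooled list and at 2.5 kb. Its unmarked genes were Hoxb13, Hoxd10, Hoxd12 and Hoxc9 to Hoxc12. The other endoderm list had 12 of 16 (13 and 11), without Neurog3, Ins2, Sftpc and Vil1. The neuronal call was also lost at 0.5 kb and with 1 start per gene.

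In 5 lists every member was marked. The lists of the cell cycle (20 of 20), ribosomal proteins (20 of 20), chromatin modifiers (20 of 20), signalling ligands and receptors (25 of 25) and housekeeping genes (15 of 15) had a peak at every member in both replicates and passed the exact test as higher (odds ratios 20.8, 20.8, 20.8, 25.9 and 15.8; adjusted p = 0.00144, 0.00144, 0.00144, 0.000581 and 0.00907). With no unmarked member, each of these odds ratios rests on the constant added to each cell and follows the size of its list. The imprinted list had 15 of its 16 coding members marked (15 and 15; odds ratio 5.25, exact test, adjusted p = 0.0252), with no peak at Ndn. The nearest replicated peak lay 1.65 kb from a start of Ndn. The cell cycle call was lost within CpG classes, the chromatin and imprinted calls with 1 start per gene, and the imprinted call, with an odds ratio of 4.42, without promoters of repeated sequence. With 18 of its 20 members CpG-rich, the cell cycle list could not pass as higher within CpG classes even with all 20 marked, so that loss decides nothing.

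The next question was how broad the mark was at marked genes. Neighbouring peaks up to 1 kb apart were merged into domains, and the median breadth of the domains at each list's marked genes was set against 10000 random lists of marked genes of the same size. A gene's breadth was that of the broadest domain at any of its starts. The random lists were not matched on the number of starts per gene. Haem biosynthesis genes had the broadest domains, with a median of 7016 bp (quartiles 5095 and 7872; 6506 bp in replicate 1 and 5669 bp in replicate 2) against 2234 bp in random lists. Erythroid genes followed with 5648 bp (6021 and 5206 bp), and stem and progenitor genes with 4918 bp (4407 and 4642 bp). For each of these 3 lists p was 0.0002, the smallest that 10000 random lists can give, and the adjusted p was 0.0011. Hmbs, the third enzyme of haem synthesis, had a domain of 11 kb (12.2 and 11.6 kb in replicates 1 and 2) and Slc25a38, a mitochondrial glycine carrier, 8.28 kb (8.65 and 5.24 kb). Among erythroid genes Ldb1, a cofactor of GATA1 complexes, had 10.9 kb (10.7 and 10.8 kb) and Bcl11a, a repressor of embryonic globin genes, 10.1 kb (9.99 and 10.03 kb). Among progenitor genes Lyl1 had 9.14 kb and Meis1 8.94 kb. The domain of Hmbs also held the start of H2afx and that of Ldb1 the start of Pprc1; with merging on overlap only, Hmbs had 6.28 kb, Ldb1 5.48 kb, Lyl1 5.27 kb and Slc25a38 4.1 kb, and the calls of the 3 lists stayed. The adult globin genes had 2.80 kb at Hbb-bt, 0.416 kb at Hbb-bs, 1.10 kb at Hba-a1 (1.04 and 0.371 kb) and 0.978 kb at Hba-a2. Only at Hbb-bt did a peak reach a start. The nearest peak lay 0.551 kb from a start at Hba-a1, 0.698 kb at Hba-a2 and 0.938 kb at Hbb-bs. These genes were singled out after their values were seen. Windows repeated in the genome made up 84.8% of the Hba-a1 promoter, 91.2% at Hba-a2, 26.8% at Hbb-bt and 17.2% at Hbb-bs.

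**Figure D2:**
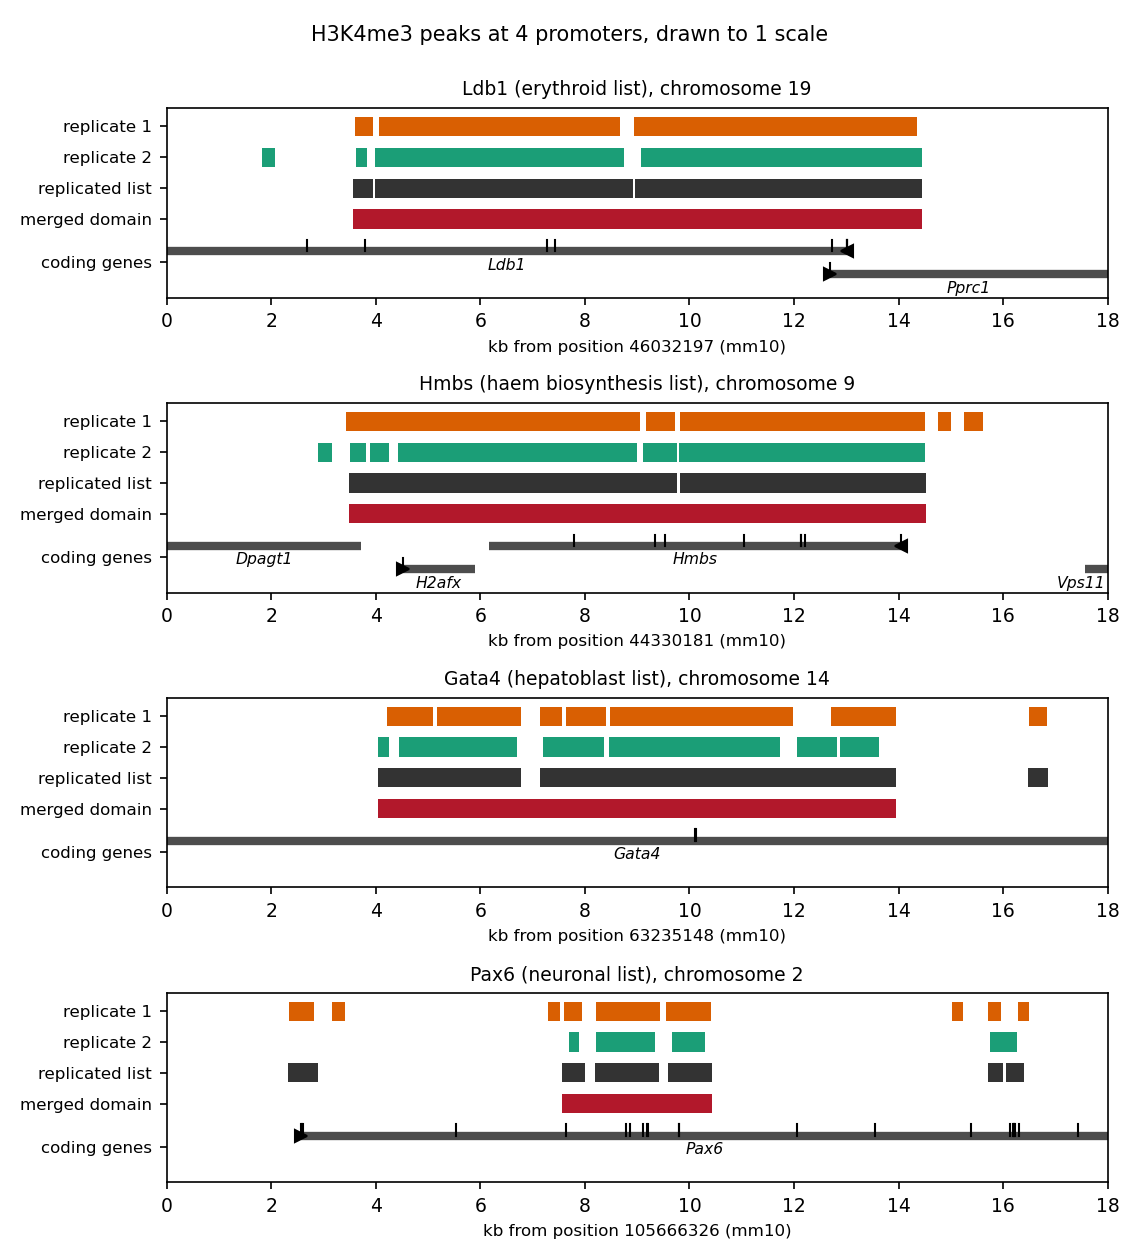
Peaks at 4 promoters in windows of 18 kb (x axis, kb along the chromosome, mm10). Tracks show the peaks of replicates 1 and 2 and of the replicated list, the merged domain (Ldb1 10.9, Hmbs 11, Gata4 9.91 and Pax6 2.86 kb) and the coding genes, with starts as ticks and 5' ends as arrowheads.

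Another 7 lists had broader domains than random lists. Their medians were 4355 bp for housekeeping genes (4075 and 4144 bp), 4204 bp for the mesenchymal list (4193 and 4082 bp), 3917 bp for ribosomal proteins (4056 and 3784 bp), 3779 bp for imprinted genes (4058 and 3046 bp), 3701 bp for signalling genes (3573 and 3782 bp), 3423 bp for the cell cycle (3717 and 3508 bp) and 3133 bp for chromatin modifiers (3236 and 3144 bp), with adjusted p from 0.0011 to 0.0179. The mesenchymal list reached 10.9 kb at Hand2 and 9.91 kb at Gata4. The imprinted list reached 10.1 kb at Igf2, the signalling list 8.19 kb at Hes1 and 7.98 kb at Ptch1, and the cell cycle list 8.11 kb at Pcna and 6.13 kb at Ccnd1. Among ribosomal and housekeeping genes, Rps18 had 7.30 kb, Rps2 6.88 kb and Polr2a 5.55 kb; Hmbs, which is in the haem list too, was the broadest housekeeping gene. Among chromatin modifiers, Setd1b, a methyltransferase of H3K4, had 10.9 kb (12.2 and 10.5 kb) and Tet3 7.0 kb (4.34 and 4.19 kb). With merging on overlap only, Igf2 had 4.31 kb, Hes1 4.78 kb, Pcna 3.55 kb, Ccnd1 3.38 kb, Polr2a 3.3 kb and Tet3 4.53 kb. The call of the chromatin modifiers was lost among peaks at or above the median fold, where their median was 2747 bp, at percentile 93.2 of random lists.

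Hepatoblast domains had a median of 2824 bp (2991 and 3009 bp), at percentile 98.2 of random lists, and missed the threshold with an adjusted p of 0.0519. They passed it as broader in either replicate's own list, in the pooled list, among peaks at or above the median fold, with merging up to 3 kb and with domains at 1 coding gene only. The list was internally uneven. Gata4 had a domain of 9.91 kb (9.74 and 9.58 kb), Prox1 8.28 kb (8.21 and 8.15 kb), Tbx3 7.62 kb and Onecut2 7.28 kb. The serum protein genes Alb, Afp, Ttr and Ahsg had 1.53, 1.6, 1.64 and 0.567 kb. The members from Tbx3 to Ahsg were picked after their values were seen, and no test compared these groups.

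Narrower domains than random lists were found at 4 lists. The marked genes of adult hepatocyte metabolism had a median of 432 bp (345 and 336 bp in replicates 1 and 2, adjusted permutation p = 0.0011), those of coagulation and complement 986 bp (1029 and 1024 bp, adjusted p = 0.0028), those of other endoderm 1047 bp (1338 and 814 bp, adjusted p = 0.00147) and those of megakaryocytes 1060 bp (1041 and 971 bp, adjusted p = 0.00609). Within them Fgg reached 3.25 kb, Plg 1.87 kb (1.97 and 0.933 kb), Sox9 4.49 kb, Barx1 4.21 kb, Itga2b 4.17 kb and Gp1ba 3.19 kb (1.42 and 2.78 kb). In the pooled list the coagulation call was lost and the megakaryocyte median was 3197 bp, above the random lists; at or above the median fold at most 2 genes of each list stayed marked, too few for the test. The other lists did not pass: endothelial 2034 bp (2061 and 2087 bp), Hox 2015 bp (2104 and 1826 bp), neuronal 1721 bp (1707 and 1462 bp), macrophage 1670 bp (1409 and 703 bp), lymphoid 1651 bp (1693 and 1722 bp), pluripotency and germ line 1351 bp (1381 and 924 bp) and muscle 1264 bp (789 and 1520 bp). In a single replicate's list the macrophage, neuronal and pluripotency lists (replicate 2) and the muscle list (replicate 1) passed as narrower. Macrophage and muscle also did so in the pooled list, and macrophage, neuronal, muscle and lymphoid with merging on overlap only. Their broadest members included Gata4, which is in the hepatoblast and mesenchymal lists too, Egfl7 at 4.68 kb, Dlx2 at 4.28 kb (4.38 and 2.74 kb), Pax6 at 2.86 kb, Spi1 at 2.6 kb, Lck at 2.32 kb, Ebf1 at 2.02 kb, Klf4 at 4.06 kb, Prdm1 at 3.52 kb, Tbx5 at 2.78 kb and Hand1 at 4.83 kb (4.56 and 2.64 kb). Hoxb3 and Hoxb4 shared a domain of 9.40 kb that was 3.6 and 3.40 kb at these genes in replicate 1 and 5.97 and 3.80 kb in replicate 2. Cd68 had 3.65 kb, but 6.10 kb in replicate 1 and 0.200 kb in replicate 2. The Hox list was narrower without merging (1355 bp) and broader with merging up to 3 kb (4608 bp).

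**Figure D3:**
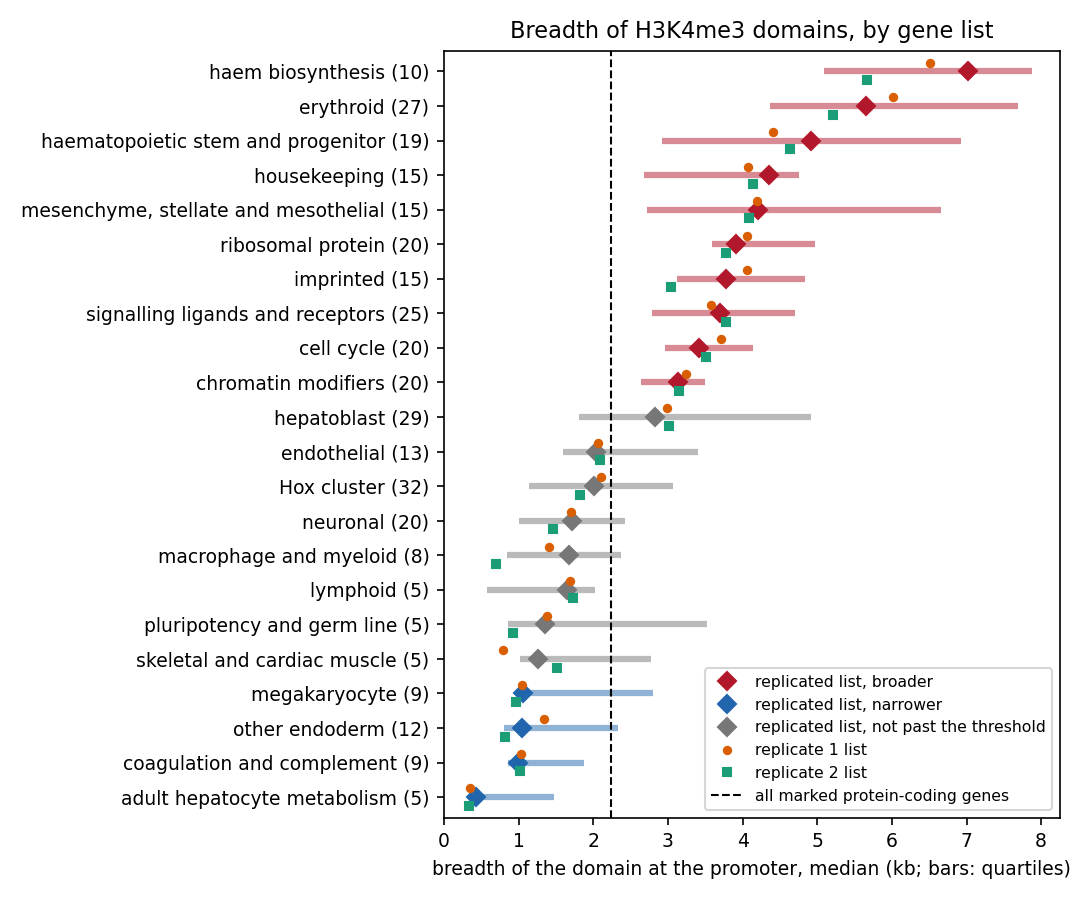
Median breadth of the H3K4me3 domain at the marked genes of each list (x axis, kb; horizontal bars are quartiles). Diamonds are the replicated list, coloured by the call against 10000 random lists, and circles and squares are replicates 1 and 2, and the dashed line is the median of all marked coding genes, 2233 bp, far exceeded by haem biosynthesis at 7016 bp and erythroid genes at 5648 bp.

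The broadest 5% of domains were 1018 of 20356 domains, each at least 4421 bp long, with 1276 of the 14533 marked coding genes; 924 of them (90.8%) overlapped the broadest 5% of replicate 1, 877 (86.1%) that of replicate 2 and 809 (79.5%) both. Erythroid genes supplied 19 of their 27 marked members, haem biosynthesis 8 of 10, progenitor genes 11 of 19 and hepatoblast genes 8 of 29. Signalling genes supplied 10 of 25, ribosomal protein genes 7 of 20, housekeeping genes 6 of 15, mesenchymal genes 6 of 15, imprinted genes 5 of 15, Hox genes 6 of 32, cell cycle genes 4 of 20, chromatin modifiers 3 of 20, endothelial genes 2 of 13, and muscle and other endoderm genes 1 each. The neuronal, megakaryocyte, macrophage, lymphoid, adult hepatocyte, coagulation and pluripotency lists supplied 0. The broadest was at Nr2f2, which encodes the nuclear receptor COUP-TFII, at chromosome 7, 70349763 to 70363124 (13.4 kb; 12.8 and 18.1 kb in replicates 1 and 2). Next came the domains at Gtpbp1 and Josd1 (13.2 kb), at Ppp1r9b (12.4 kb), at Prdx2, Junb and Rnaseh2a (12.2 kb; 16.6 kb in replicate 1, but 7.2 kb at Junb and 4.23 kb at the others in replicate 2), at Bahcc1 (11.6 kb) and at Irs2, an insulin receptor substrate (11.5 kb). Gata6, a factor of endoderm and mesoderm, had 11.5 kb (11.7 and 11.2 kb) at chromosome 18, 11047813 to 11059319. The domains at Tnrc18 (11.5 kb), at Akt1s1, Pnkp and Tbc1d17 (11.2 kb; 13.7 kb in replicate 1, but 5.84, 5.84 and 4.91 kb in replicate 2), at H2afx and Hmbs (chromosome 9, 44333661 to 44344701) and at Mafg and Sirt7 (10.97 kb; 12.7 kb in replicate 1, but 7.73 kb at Mafg and 2.0 kb at Sirt7 in replicate 2) followed. The rest of the 20 broadest lay at Ldb1 and Pprc1, Setd1b, Hand2, Igf2bp3, Glrx5, an enzyme of iron-sulphur cluster assembly (10.5 kb), Ring1, Rxrb, Slc39a7 and H2-Ke6, Cks1b and Shc1, Irs1, and Mir142hg, the host gene of a microRNA of blood cells (10.4 kb; 10.2 and 4.84 kb). With merging on overlap only, domains were over 1.5 times narrower at 45 of the 69 marked genes named by rule, Nr2f2 among them at 8.64 kb. Peaks at or above the median fold put 767 coding genes into the broadest 5%.

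Away from annotated starts the mark was narrower and weaker. Peaks over 5 kb from every start of any gene type numbered 3468 (14.3%, interval 13.9 to 14.8), against 5015 in replicate 1 and 4052 in replicate 2. Their median width was 581 bp and their median fold 5.35, and 82.4% had a counterpart in both replicate lists, against 96.3% of the peaks at coding starts. Genes held 44.4% of them and 55.6% were intergenic. A second annotation (RefSeq) placed a start within 1 kb of 407 of them (11.7%, interval 10.7 to 12.8), against 5.09% of shuffled peaks. The shuffled peaks could land within 5 kb of the first annotation's starts, where no distal peak can lie. The 2 shares are therefore not directly comparable. The 5 with the highest fold were all intergenic and found in both replicates. That at chromosome 1, 171037663 to 171038732 (fold 69.5) lies 18.7 kb from the coding gene Fcgr4, and that at chromosome 1, 86486701 to 86489176 (fold 53.5) lies 37.6 kb from Ptma. The others were at chromosome 1, 171101550 to 171103927 (fold 50.9, 9.99 kb from Cfap126), chromosome 17, 83861259 to 83863158 (fold 50.4, 13.3 kb from Haao) and chromosome 12, 8640365 to 8641750 (fold 49.8, 32.4 kb from Pum2). Nearer than the coding gene lay the snRNA gene Gm26110 (9.70 kb, peak near Fcgr4) and the pseudogene Rpl30-ps6 (13.0 kb, peak near Ptma). The lincRNA gene C430042M11Rik (6.84 kb) lay nearer than Haao. At or above the median fold only 405 distal peaks were left, and over 10 kb from a start 2195.

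The error between the replicates was concentrated in weak peaks. Of the peaks of replicate 1, 74.7% overlapped a peak of replicate 2 by at least 1 bp (interval 74.2 to 75.2), and 87.5% of the peaks of replicate 2 overlapped one of replicate 1 (interval 87.2 to 87.9). Shuffled lists gave 2.68% and 3.04%. In the lowest decile of fold enrichment 28.8% of replicate 1 peaks and 56.8% of replicate 2 peaks had a counterpart, whereas in each of the 5 highest deciles at least 99.6% did. Peaks without a counterpart had a median width of 250 bp in replicate 1 and 236 bp in replicate 2, against 1167 and 1073 bp for those with one. The replicated list kept 77.3% of the pooled peaks (interval 76.8 to 77.7), from 13.3% in the lowest decile of fold to 100% in the 5 highest. Genes with a promoter peak in only 1 replicate had a median fold of 3.5 in replicate 1, whose peaks had a median of 6.35, and of 3.74 in replicate 2, whose peaks had 9.54. The highest folds among them were at Igfn1 (16.6), Rs1 (12.1), Lnx1 (11.98), Olfr56 (7.0) and Ttc9b (6.30) in replicate 1. In replicate 2 they were at 1700017N19Rik (42.0), Cldnd2 (23.8), Lor (22.8), Tmsb15b2 (8.53) and Cfap44 (6.89). At all of these except Ttc9b and Cfap44 a peak at the start overlapped a peak of the other replicate, whose nearest peak lay 1.01 to 1.11 kb from a start, just past the limit of 1 kb. Among all such genes a promoter peak overlapped one of the other replicate at 11 of 226 in replicate 1 and 6 of 107 in replicate 2.

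**Figure D4:**
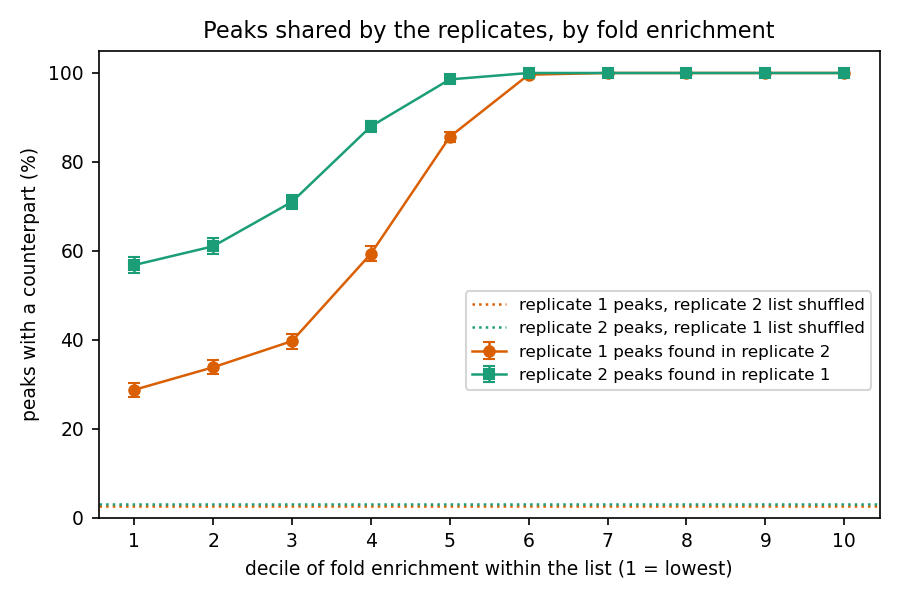
Share of the peaks of each replicate that overlap a peak of the other (y axis, percent) by decile of fold enrichment within the list (x axis, 1 is lowest). Error bars are Wilson 95% intervals and dotted lines are the shares with the other list shuffled, 2.68% and 3.04%, and the share rises from 28.8% in replicate 1 and 56.8% in replicate 2 to 100% in the highest decile.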

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

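The test of weak calls and the separate test of promoters with mostly repeated sequence were chosen only after the result was seen. A signal outside the main measurement was found on scaffolds that belong to no chromosome: 9 peaks of the replicated list lay on 6 unplaced or unlocalized scaffolds, with fold enrichments from 3.88 to 35.1. The design has 1 group, so no biological explanation was tested here beyond a different mixture of cells in the pools.

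The broad domains at erythroid and haem biosynthesis genes (37 marked genes, median 5.89 kb against 2.24 kb in random lists) could arise where neighbouring promoters merge into 1 domain. With single peaks at 1 coding gene only, the median of the 31 genes left was 4.65 kb against 1.96 kb, at percentile 100 of random lists. Merging of separate peaks, or of the promoters of different coding genes, is thereby excluded as the whole cause. A single peak may still span several starts of 1 gene or a non-coding start, and the random lists were not matched on these. Random lists matched on fold enrichment gave 2.25 kb and those matched on CpG number 1.99 kb, again with the observed median at percentile 100 and 100. Taken singly, neither the highest fold at a gene nor the CpG number at its 5' end therefore accounts for the breadth. A broad domain may lie at another start, so CpG content under the domain itself was not tested.

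Peaks called in 1 replicate only may be calls near the detection limit. Of the peaks at or above the median fold, 99.9% in replicate 1 and 100% in replicate 2 had a counterpart in the full list of the other, but this restates the overlap by decile of fold, so it decides nothing and the explanation stays open. A GC bias between the libraries also stays open, with a median GC 2.34 percentage points higher in peaks of replicate 1 only (51.9%) than in those of replicate 2 only (49.6%). A different mixture of cells in the pools also stays open. Of 250 genes of the cell type lists, 14 were marked in replicate 1 only, 5 of them Hox genes (Hoxa10 and Hoxc8 to Hoxc11), and 3 in replicate 2 only (C1qa, Cd79b and Oit3), with a permutation p of 0.0676 for an uneven spread over 13 lists.

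The 139 CpG-rich promoters without a peak may lack it where reads cannot be placed. As before, a peak at any start of the gene counted, also where it lay away from the classed 5' end. Of the 139, 64 (46.0%, interval 38 to 54.3) consist mostly of sequence repeated elsewhere, against 0.355% of the marked ones. Of all 98 mostly repeated CpG-rich promoters, 65.3% had no peak, against 0.779% of the others, so repeated sequence is consistent with the first part of the pattern. Of the other 75, 55 had no repeated window and the rest up to 46.7%; this part was chosen by the same measure, so no separate test was made and the reason for the missing peaks stays open. A peak between 1 and 5 kb from a start was found at 12 of the 139 (8.63%, interval 5.01 to 14.5). Where the surrounding sequence is repeated too, such a peak could be missed, but 67 of the 75 others had none either. A start displaced by up to 5 kb therefore does not account for most of these promoters, and larger distances were not searched. The 67 with neither feature included the germ line genes Ddx4, Mael, Sycp1 and Sycp3 and the developmental regulators Otx2, Six3, Pax1 and Pax7, named after their values were seen. Each of these regulators had a promoter peak in 1 replicate, Otx2 in replicate 2 and the others in replicate 1.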

How the results depend on the processing

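The alternatives without promoters of repeated sequence and with domains at 1 coding gene only were chosen only after the result was seen. A count was taken as unchanged within 1.5 times, and another value within 1 SD between the replicates or its 95% interval. On that basis 51 values of the main results under an alternative stayed and 25 moved. Marked coding genes ranged from 11928 to 14752 and lists called broader from 10 to 12, and the CpG contrast kept its direction and its side of the threshold. For the marking of single lists, 160 values kept direction and side of the threshold, 17 became weaker, 9 stronger and 12 reversed; for breadth these were 122, 2, 17 and 6. Breadth at named genes changed by over 1.5 times in 101 of 403 values, 45 of them with merging on overlap only, 16 without replicate 1 and 5 without replicate 2. No paired analysis was possible because the series has only 1 group. Read depth is unknown and limits what a missing peak means.

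The share of replicate 1 peaks found in replicate 2 was 71.3% with 50% of the shorter peak, 62.9% with 50% of both, and 86.7% among above-median peaks of each list; in the other direction these were 83.9%, 71.3% and 99.3%. All above-median pooled peaks (100%) were replicated. The share of peaks at a coding start ranged from 56.4% to 61.7% leaving out each replicate, and was 56.5% in the pooled list, 91.8% among above-median peaks and 73.6% at 2.5 kb. The shortest of the broadest 5% of domains ranged from 4211 to 4387 bp leaving out each replicate, and was 4584 bp in the pooled list, 3693 bp merging on overlap only and 5542 bp at 3 kb. Above-median peaks left 767 coding genes in the broadest 5% and 405 distal peaks (5140 in the pooled list), and 2195 peaks were distal at 10 kb. Lists called higher fell from 11 to 6 with the 5' end only. Lists called lower went from 4 to 10 among above-median peaks and to 2 within CpG classes. Lists called narrower, 4 in the main result, were 5 to 7 leaving out each replicate, 9 merging on overlap only and 0 among above-median peaks, where the megakaryocyte, macrophage, lymphoid, adult hepatocyte, coagulation, muscle and other endoderm lists had under 3 marked genes and gave no value.

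Odds ratios reversed among above-median peaks for hepatoblast (0.952), megakaryocyte (0.246), endothelial (0.217), mesenchymal (0.837), neuronal (0.279), other endoderm (0.144) and Hox genes (0.193). They reversed within CpG classes for macrophage (1.14), coagulation (1.43) and other endoderm (0.955), for other endoderm with the 5' end only (0.755), and for macrophage without replicate 2 (1.04; without replicate 1, 0.642). Median breadth reversed for megakaryocyte in the pooled list (3197 bp), for endothelial (3387 bp), Hox (2500 bp) and pluripotency genes (3518 bp) among above-median peaks, and for muscle (2779 bp) and Hox genes (4608 bp) at 3 kb. Fewer peaks entered with the above-median alternative by construction; otherwise the cause was not tested.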

Other observations

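The gene families, non-coding genes and distances described here were chosen only after the result was seen. The Gata family, transcription factors of blood and endoderm, had a promoter peak at all 6 genes, with a median breadth of 8.57 kb. Clustered histone genes were marked at 56 of 67, Fox factors at 36 of 44 and proteasome genes at 39 of 40. Clustered protocadherin genes, used in neurons, were marked at 15 of 56, interleukin genes at 8 of 37 and genes of cytochrome P450 family 2 at 12 of 57. No defensin gene (0 of 64) and no major urinary protein gene (0 of 22) was marked. Chromosome 12 had the largest share of marked coding genes (80.2%, interval 77.0 to 83.1), the X chromosome had 50.7% (interval 47.6 to 53.9), and the Y chromosome had 4 of 183 (2.19%). Repeated sequence in promoters was not taken into account for these families and chromosomes, so a missing peak there may be one that could not be called.

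Among non-coding genes, the imprinted H19, Meg3, Kcnq1ot1 and Airn had domains of 3.28, 3.33, 3.52 and 2.09 kb. Xist, which silences the X chromosome in female cells, had 3.99 kb, in pools of both sexes. Malat1 and Neat1, nuclear RNAs, had 9.84 and 8.02 kb (Neat1 4.25 and 7.81 kb in replicates 1 and 2), the microRNA host gene Mir17hg had 4.58 kb and Dleu2 7.78 kb (4.91 and 4.94 kb in replicates 1 and 2), while Hotair and Hottip, at the Hox clusters, had none. Of 5854 lincRNA genes 14.3% had a peak at a start, and 8.06% of those far from any coding start did; for antisense genes these shares were 35.4% and 7.04%, and for microRNA genes 15.4% and 4.58%. Processed pseudogenes had 1.75%.

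A distal peak lay within 50 kb of 14 of 30 hepatoblast genes (46.7%) and of 11 of 21 neuronal genes (52.4%), against 19.2% of other coding genes for both lists (Fisher's exact test, adjusted p = 0.00737 for each). None of the other 20 lists passed, among them erythroid genes with 9 of 28. Gene spacing and the number of starts per gene were not controlled.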
